A study of Mus musculus with 4 samples.

How the data were processed

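Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in mouse thymocytes of the DN3 stage. DN3 cells are CD4/CD8 double-negative precursors at the stage where the T cell receptor beta gene is rearranged. Per the labels' protocols, DN3 cells from wild-type thymus were obtained by flow sorting and then separated magnetically with a biotin-coupled antibody against the adhesion molecule EpCAM. Labelled cells were retained as the EpCAM-positive fraction, and the cells that ran through unlabelled formed the EpCAM-negative fraction. Libraries were made with a Vazyme TruePrep transposase kit, per the labels' protocols. Each fraction has 2 libraries, numbered 1 and 2 in the labels. Nothing in the labels says that they came from separate mice, so the spread between libraries may be technical.

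The submitters' processing notes name FastQC, Trim Galore, Trimmomatic, Bowtie2, SAMtools, Picard, bedtools, deepTools and MACS3, and the mouse build mm10 (GRCm38). Versions, the role of each tool, the treatment of duplicates, any shift of reads for the transposase offset and the settings of the peak caller are not given in the sources used here. The deposited data were 1 list of narrow peaks per library, so peaks were called per library and not on pooled libraries. Each deposited list gives a peak's position and summit, a display score, a fold enrichment over local background, and the −log10 of its p-value and of its q-value, all made by the authors' peak caller. These values belong to the single peak, and scores, folds and −log10 values were used to describe, rank or filter peaks within a list. Apart from the lowest −log10 q of each list, which is stated per library, they were compared between libraries only in choosing summits and in thinning. A region's strongest summit was that of its peak with the highest −log10 q in any list. Thinned EpCAM-positive peaks had to reach a −log10 p of 4.89, set from the EpCAM-negative lists.

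Lists held 24598 to 29030 peaks. Read totals are not given in the sources used here, so depth is not known as a count of reads. For each peak, the pileup at the summit and the local background were solved from the deposited fold and −log10 p, using the caller's definitions of a fold with 1 added to both terms and a Poisson p-value, with a tolerance of 0.01 on −log10 p. This worked for 99.9885% to 99.9959% of the peaks per list. The solved pileup is called summit fragments here, although whether the caller counted fragments or reads is not given. The lowest common background served as a relative measure of depth. A difference in the share of fragments lying outside peaks would move it too. Confidence intervals cover counting error only.

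Peaks on chromosomes 1 to 19, X and Y were merged across the 4 lists wherever they overlapped by at least 1 bp, and the merged intervals are called regions. A region was EpCAM-positive-only when called in both EpCAM-positive libraries and in neither EpCAM-negative library, and EpCAM-negative-only in the reverse case. The 4 mixed patterns, in which a region was called in exactly 1 library of each fraction, have the same number of calls and served as the level without a difference between fractions. With 2 libraries against 2 the smallest two-sided exact permutation p is 0.33, for a single region as for a value per library, so regions were counted and not tested one by one. List overlap was the Jaccard index, the bases covered by both lists over those covered by either. Within-fraction minus between-fraction overlap was set against the 2 other splits of the 4 libraries.

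Each region was assigned to the nearest of 22117 protein-coding or T cell receptor genes of RefSeq GRCm38.p6 within 100 kb, measured from its strongest summit. The annotation table used here gives gene start and end without strand, so the planned distance to a transcription start site was replaced by the distance to the nearer gene end, which is either the start or the end of transcription. A region given with a gene and no distance is one assigned to it, which can lie up to 100 kb from its nearer end. Exons, introns and untranslated regions were not annotated for the same reason. A region at a gene end has its summit within 1000 bp of one. A planned search for 23 sequence motifs was not run, because no genome sequence was used here.

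The share of regions at gene ends was compared by Fisher's exact test, two-sided, with exact Clopper-Pearson intervals at 95%. For 21 gene lists, Fisher's exact test compared the share of group-only regions in the list with that among other regions called in at least 2 libraries, over 42 tests with Benjamini-Hochberg adjustment and a threshold of 0.05. A further 21 tests compared the directions with each other. Regions are not biological replicates, so these p-values describe these lists. The genes named are Epcam and 8 genes of the double-negative stages; the 15 genes per direction whose region ranked highest by the lower of its within-list percentiles of −log10 q; up to 4 members per gene list and direction, ranked the same way; and up to 8 genes per direction with the most group-only regions, at least 3. Some genes that this rule selects are not reported here. Lists, groups, the planned tests and this rule were fixed before the data were examined. Comparing the directions with each other, at gene ends and in the 21 tests, was not planned, nor were the mixed splits for gene ends. For gene ends, the plan set each group-only set against the regions called in all 4 libraries, by region midpoint and not by summit.

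The settings varied were a −log10 q of at least 5; lists of equal length (the 24585 strongest peaks each); an overlap of at least 50% of the shorter peak; windows of 250 bp either side of each summit; strong presence with strict absence (−log10 q of at least 5 in both libraries and no peak of the other fraction within 500 bp); other gene assignments, backgrounds and end windows; and leaving out each library. A depth-scaled set, a thinning of the EpCAM-positive lists and differences in peak number within same-numbered pairs were added after the data had been seen. The depth-scaled set holds regions whose lower summit pileup, scaled by the background levels, would have fallen under the 5th percentile of each other list with a Poisson probability below 0.05. The local background of a region, which enters a call, was not used in this. EpCAM-positive-only pileups were scaled down and EpCAM-negative-only pileups scaled up. The former thus needed a higher pileup to enter, also relative to their own background, which tends to lower the ratio of the counts. Thinning drew each EpCAM-positive summit pileup binomially to the mean EpCAM-negative background, over 20 draws.

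The procedures were tested on simulated lists made for the comparison of EpCAM-positive-only and EpCAM-negative-only regions. Summit fragments were solved correctly for 100% of 2937 peaks, and 200 of 200 planted regions were recovered in each direction. The planted lists held no missed calls, no peaks of a single library and no depth difference. Recovery there checks the code and not the group-only calls in the real lists. Gene lists planted at 3 times the EpCAM-positive-only background rate were called in 41.9% of 420 cases, and in 78.75% of 80 cases for lists of at least 80 regions. These calls used a Bonferroni cut over 42 tests in place of the Benjamini-Hochberg adjustment. None of the shuffled sets, 0 of 20, gave a call in the EpCAM-positive-only direction. The EpCAM-negative-only direction was neither planted nor shuffled in the gene list tests. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.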

Results

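Open chromatin was mapped in DN3 thymocytes separated into an EpCAM-positive and an EpCAM-negative fraction, with 2 ATAC-seq libraries per fraction. The title of the series places EpCAM on a subset of double-negative thymocytes with a part in T cell production, and the comparison asks where accessible regions differ between DN3 cells with and without it. The EpCAM-positive lists held 26029 (replicate 1) and 29030 (replicate 2) peaks, covering 12.9 Mb in each case. The EpCAM-negative lists held 24598 and 25924 peaks, covering 10.8 and 10.6 Mb. The mean was 27530 ± 2122 peaks against 25261 ± 938 (SD, n = 2 per fraction; two-sided exact permutation p = 0.33, the smallest this design allows). The background solved from the peaks was 0.388 and 0.383 fragments per base in the EpCAM-positive libraries and 0.290 and 0.286 in the EpCAM-negative ones, 1.34 times higher in the EpCAM-positive mean. The lowest −log10 q listed was 2.07 and 2.02 in the EpCAM-positive lists and 1.32 and 1.34 in the EpCAM-negative lists, so the fractions differed in this background and in the lowest value listed. Read totals are not known, and whether the lists of both fractions were called with the same settings is not given in the sources used here.

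Of the 8 genes of the double-negative stages, all but Ptcra had at least 1 assigned region called in all 4 libraries. Ptcra had 2 assigned regions, 0 called in all 4 libraries and 1 EpCAM-negative-only. A peak from 46751687 to 46752507 on chromosome 17, outside Ptcra (46755663 to 46763712), was called in all 4 libraries. Its −log10 q was 78.9 and 102 in the EpCAM-positive and 58.8 and 67.4 in the EpCAM-negative lists. It was not assigned to Ptcra, because the end of another gene lay nearer. Il2ra, which encodes the CD25 chain of the interleukin-2 receptor that marks DN2 and DN3 cells, had 8 assigned regions, of which 5 were called in all 4 libraries and none in a single fraction's pair alone. Bcl11b, a transcription factor of T lineage commitment, had 5 of 11 regions in all 4 libraries, and Notch1, the receptor that drives the T cell fate, had 4 of 10. Gata3 had 4 of 6, Tcf7, encoding TCF1, had 3 of 7, and Kit, the stem cell factor receptor of earlier precursors, had 1 of 4. The strongest Notch1 region by −log10 q in the EpCAM-negative lists lay outside the gene on chromosome 2 (mm10, 26513139 to 26514034), with 37 and 47 summit fragments in the EpCAM-positive and 68 and 63 in the EpCAM-negative libraries. At Tcf7, the region on chromosome 11 from 52313987 to 52314794 had 77 and 70 summit fragments in the EpCAM-positive and 36 and 58 in the EpCAM-negative libraries. These 2 regions were picked after their values had been seen, and their pileups are not adjusted for depth and were not tested. Cd44, an adhesion receptor that is down-regulated before the DN3 stage, had 3 of 7 regions in all 4 libraries, with 1 EpCAM-positive-only region 42466 bp and 1 EpCAM-negative-only region 46913 bp from the gene.

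Epcam itself, the gene of the molecule used for the separation (chromosome 17, 87635979 to 87651127), had 7 assigned regions and none called in all 4 libraries. Of these, 6 were called in at least 1 EpCAM-positive library and 3 in at least 1 EpCAM-negative library. The strongest one within the gene, at 87636682 to 87637250 and 816 bp from its nearer end, was called in both EpCAM-positive libraries with 13 and 11 summit fragments and in EpCAM-negative replicate 2 with 10, and not in EpCAM-negative replicate 1. At the same end of the gene, a peak from 87635837 to 87636050 was called only in EpCAM-positive replicate 2 and a peak from 87636057 to 87636296 only in EpCAM-positive replicate 1, with 8 and 10 summit fragments. The EpCAM-positive-only region assigned to Epcam lay 64330 bp away, at 87571441 to 87571790, with 10 summit fragments in each library. A region at 87602070 to 87602396, 33740 bp from the gene, had 14 and 20 summit fragments in the EpCAM-positive libraries and 9 in EpCAM-negative replicate 1. An exact test of 1 gene with 2 lists against 2 cannot give a two-sided p below 0.33, and none was run.

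**Figure D1:**
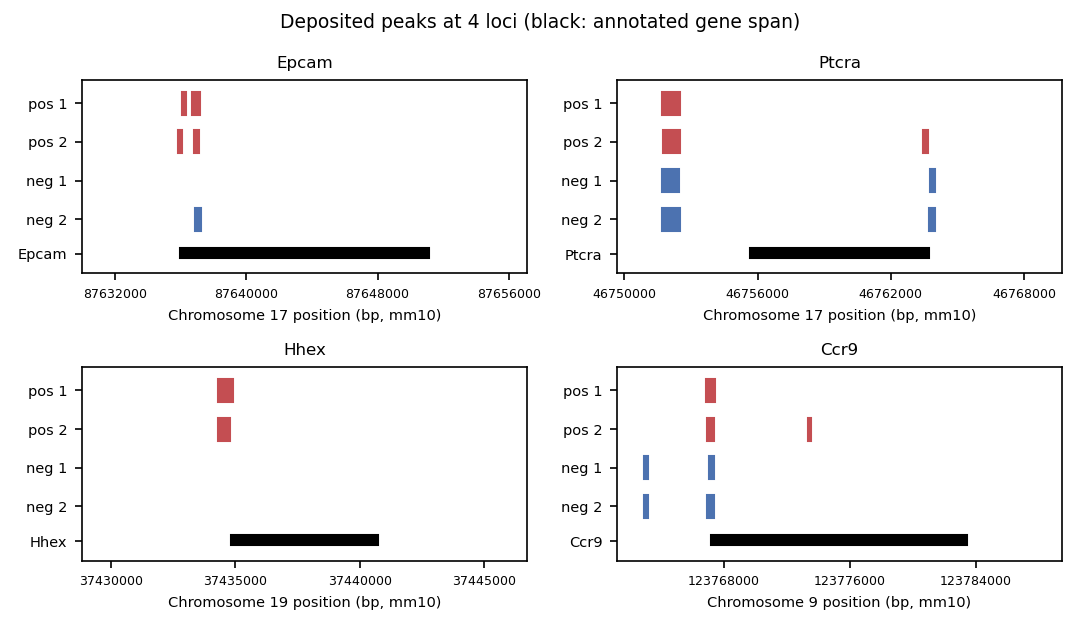
Deposited peaks per library (rows; red, EpCAM-positive; blue, EpCAM-negative) along 4 loci, with position in bp (mm10) on the x axis and the annotated gene span in black. The Epcam peak at 87636682 to 87637250 is present in 3 of the 4 libraries, the EpCAM-negative peak at Ptcra lies beside a peak of EpCAM-positive replicate 2, and the Hhex and distal Ccr9 peaks are each present in 1 fraction. Beyond the other end of Ptcra, a peak is present in all 4 libraries.

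Across the genome, regions restricted to the EpCAM-positive pair were more numerous than those restricted to the EpCAM-negative pair. Of 36224 regions, 16761 (46.3%) were called in all 4 libraries and 10801 (29.8%) in 1 library. EpCAM-positive-only regions numbered 1594 against 623 EpCAM-negative-only regions, a ratio of 2.56 (95% interval 2.33 to 2.81). All but 93 of the former were assigned to 1383 genes, and all but 80 of the latter to 522 genes. The EpCAM-positive-only count lay above all 4 mixed patterns, which held 470, 476, 647 and 925 regions. The EpCAM-negative-only count was close to their mean of 629.5. Group-only regions were weak, with a median of 11 summit fragments for EpCAM-positive-only and 9 for EpCAM-negative-only regions against 28 for regions called in all 4 libraries. The ratio was 1.36 (1.24 to 1.49) with lists of equal length, where the counts were 1092 and 805 and both exceeded the mixed patterns (495 to 663), and 1.11 (0.934 to 1.33) in the depth-scaled set, with 274 and 246. That set asked for higher pileups in EpCAM-positive-only regions. When 1 library is left out, its fraction needs only 1 call, and the EpCAM-positive-only and EpCAM-negative-only counts became 5777 and 1190 without EpCAM-positive replicate 1, 4375 and 1544 without EpCAM-positive replicate 2, 2835 and 3247 without EpCAM-negative replicate 1, and 2922 and 2544 without EpCAM-negative replicate 2.

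**Figure D2:**
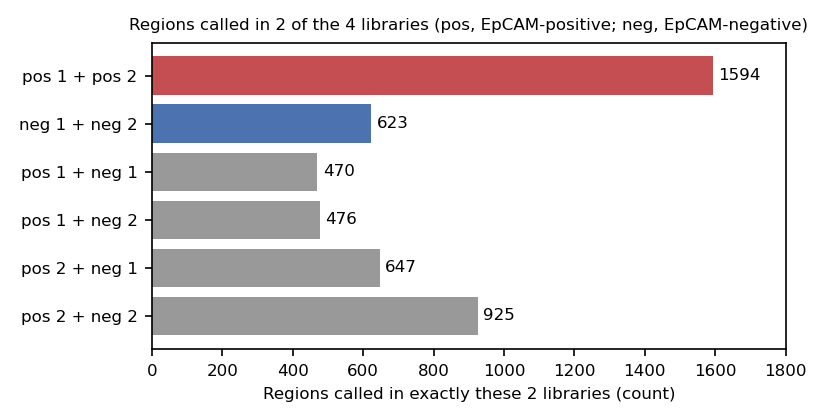
Number of regions (x axis, count) called in exactly 2 of the 4 libraries, for each pair of libraries (rows). The EpCAM-positive pair (red) reaches 1594, the EpCAM-negative pair (blue) 623, and the mixed pairs (grey) 470 to 925.

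Of the 15 highest-ranked EpCAM-positive-only regions, 11 lay within a gene and 6 at a gene end, with 15 to 44 summit fragments. Sit1, which encodes a transmembrane adaptor that restrains T cell receptor signalling, had an EpCAM-positive-only region over its end on chromosome 4 (43481937 to 43482259) with 39 summit fragments in each library. Pik3r5, a regulatory subunit of phosphoinositide 3-kinase gamma, had one over its end on chromosome 11 (68431842 to 68432532) with 40 and 42, and Agap2, a GTPase-activating protein, on chromosome 10 (127075228 to 127075623) with 25 and 26. The first 2 by rank were next to Ap3m1, a subunit of the AP-3 adaptor complex, on chromosome 14 (21032065 to 21032544; 23 and 21 summit fragments) and within Myzap on chromosome 9 (71543570 to 71544030; 25 and 19). Regions within Glipr2, Wdyhv1, Anxa2, Coro2a, Nlrx1 and Pcdhgb6, and 27505 bp from Klf13, a zinc-finger transcription factor, made up the others that had no EpCAM-negative peak within 500 bp. Those at Gm52512, Tnik and Mfsd11 had an EpCAM-negative peak 5, 143 and 92 bp away. Abr and Aopep had 4 EpCAM-positive-only regions each, and Ccdc188, Rfx1, Fam169b, Lrrc1, Cxxc5 and Sgip1 had 3 each.

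Among the EpCAM-negative-only regions, the one at Ptcra lay at a gene that is specific to this stage of T cell development. Ptcra encodes the pre-T cell receptor alpha chain, and the region was at chromosome 17, 46763711 to 46764002, 96 bp outside the gene's end, with 14 and 16 summit fragments. A peak of EpCAM-positive replicate 2 (46763471 to 46763684, 9 summit fragments) lay 26 bp from it, inside the gene. The peak beyond the other end of Ptcra, called in all 4 libraries, was stronger. Its −log10 q was 58.8 and 67.4 in the EpCAM-negative lists, against 9.65 and 11.4 for the EpCAM-negative-only region. The first by rank were 39030 bp from Lhx9, a LIM homeobox gene, on chromosome 1 (138785945 to 138786253; 19 and 17 summit fragments), within Bicral on chromosome 17 (46874245 to 46874558; 22 in each library) and within Elfn2 on chromosome 15 (78715814 to 78716082; 23 in each). Srebf2, a transcription factor of cholesterol synthesis, had one within the gene on chromosome 15 (82162118 to 82162388; 26 and 25). Nt5e, encoding the ectonucleotidase CD73, had one 54106 bp away with 10 and 14. The remaining top regions were at Xrra1, Htr2a, Gsx1, St7, Cacng6, Mbp, Cmah and Frmd4b, and at Pknox1, where an EpCAM-positive peak lay 117 bp away. Of these 15 regions, 7 lay within a gene and 2 at a gene end, with 9 to 30 summit fragments. Clec16a and Prex1 had 3 EpCAM-negative-only regions each. Over both directions, 43 of 59 named EpCAM-positive-only and 29 of 43 named EpCAM-negative-only regions were strong with strict absence, and 31 and 29 were in the depth-scaled set.

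The gene lists of T cell development held group-only regions of both kinds. The T lineage transcription factors had 7 EpCAM-positive-only and 5 EpCAM-negative-only among 144 regions. The former included regions within Fli1 (33 and 45 summit fragments), Zbtb7b, which encodes the CD4 lineage factor ThPOK (16 and 24), Runx1 (13 and 14) and Tox (22 each, 63 bp from an EpCAM-negative peak). The latter included regions at Ikzf1, which encodes Ikaros (13 each), Tox (7 and 9), Tcf12 (12 and 8) and Ikzf2 (7 and 6). Tox, Tcf12 and Ikzf2 thus had regions of both kinds. In the Notch list, 1 of 46 regions was EpCAM-positive-only, near the target gene Hes1 (33 and 27), and 2 were EpCAM-negative-only, at Ptcra and within Dtx1 (9 and 13). The pre-TCR and TCR signalling list had 7 and 5 of 112, with Cd6, Nfatc2 and Plcg1 in the first direction, Cd69, Nfatc1 and Id3 in the second, and Fyn and Lcp2 in both. V(D)J recombination genes had 1 and 1 of 24, the EpCAM-positive-only one near Dntt, which encodes terminal transferase (24 and 25), and the EpCAM-negative-only one near Rag1 (7 and 4). DN4 and double-positive stage genes had 1 and 1 of 41, within Arpp21 (14 and 15) and 4123 bp from the chemokine receptor gene Ccr9 (16 and 22). Gamma-delta T cell genes had 0 and 2 of 29, at Etv5 and Id3, and mature T cell genes 4 and 1 of 40, with Il21r, Foxo1 and Pdcd1 against Ccr4. A region at Il21r lay 77 bp from an EpCAM-negative peak.

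Progenitor legacy genes, which are active before T lineage commitment, had the lowest unadjusted p of all lists. Of their 66 regions, 9 (13.6%) were EpCAM-positive-only, against 6.27% of other regions (odds ratio 2.36, Fisher's exact p = 0.0356, adjusted p = 0.872), and 4 (6.06%) were EpCAM-negative-only, against 2.27% of other regions (odds ratio 2.78, Fisher's exact p = 0.0636, adjusted p = 0.872). The EpCAM-positive-only regions included ones assigned to Hhex, a homeobox gene (chromosome 19, 37434296 to 37434906, 330 bp outside the gene's end; 17 and 16 summit fragments), Tal1 (823 bp inside its end; 13 and 20), Lmo2 (770 bp outside; 14 and 10), Lyl1 (40858 bp away; 11 and 10) and Cd44 (42466 bp away; 9 in each library). The EpCAM-negative-only ones were over the end of Lyl1 (20 and 25), 11211 bp from Gfi1b (10 and 9), 46913 bp from Cd44 (8 and 12) and within Meis1, 44615 bp from its nearer end (6 and 8). The list did not pass after adjustment in either direction, and against regions called in exactly 2 libraries its EpCAM-positive-only odds ratio was 1.04 (Fisher's exact p = 1). In the depth-scaled set 1 of its regions, at Hhex, was EpCAM-positive-only (odds ratio 1.35, Fisher's exact p = 0.528) and 2, at Lyl1 and Gfi1b, were EpCAM-negative-only (odds ratio 3.27, Fisher's exact p = 0.131).

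The lists of other cell types that a DN3 gate could hold did not differ detectably from other regions in their share of group-only regions. The lowest unadjusted p was that of gamma-delta T cell genes among EpCAM-negative-only regions (odds ratio 3.19, Fisher's exact p = 0.141), followed by myeloid and dendritic cell genes (Fisher's exact p = 0.165). Thymic epithelial genes, the other EpCAM-bearing cells of the thymus, had 1 EpCAM-positive-only and 0 EpCAM-negative-only among 25 regions, the former 11182 bp from Krt18 (13 and 8 summit fragments). B cell genes had 1 and 0 of 14 (Igll1, 163 bp from an EpCAM-negative peak), myeloid and dendritic cell genes 1 and 2 of 32 (Itgam and Tcf4 in the EpCAM-negative-only direction), NK and innate lymphoid genes 2 and 2 of 41 (both at Tbx21 against Eomes and Klrd1), and erythroid and megakaryocyte genes 1 and 1 of 12 (both at Zfpm1).

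Some gene lists of cell state and signalling held group-only regions of both kinds, and others held EpCAM-positive-only regions alone. Immediate early and stress genes had 5 EpCAM-positive-only and 0 EpCAM-negative-only of 55 regions, including ones within Jun (61 and 60 summit fragments) and Jund (60 and 67) and near Hspa1b (22 and 13, 42 bp from an EpCAM-negative peak). The high pileups at Jun and Jund stood on a high local background, with folds of 2.46 and 2.58 at Jun and 2.44 and 3.09 at Jund. EpCAM-negative peaks lay 1198 bp from the Jun region and 623 bp from the Jund region. Glycolysis and nutrient uptake had 3 and 3 of 43, with Slc16a1, Slc2a3 and Ldha against Slc16a1 and Eno1. Cytokine receptors and the STAT5 axis had 3 and 0 of 86 (Socs3 and Jak1), apoptosis and survival 2 and 0 of 47 (Bbc3 and Cflar), and the NF-kappaB pathway 2 and 0 of 51 (Nfkbiz and Tnfrsf18). The Cflar region lay 477 bp from an EpCAM-negative peak. Adhesion and migration had 6 and 3 of 81, with Itga4, Tspan32, Itgae and Cd82 in the first direction, Ccr9 in the second and Cd44 in both. The Wnt pathway had 4 and 2 of 52, with Tle3, Tle4, Btrc and Fzd5 against Lrp5 and Btrc, and cell cycle genes 1 and 1 of 56 (Cdkn2c against Cdk6). The EpCAM-negative-only region at Btrc lay 1 bp from an EpCAM-positive peak. By Fisher's exact test with Benjamini-Hochberg adjustment over 42 tests, 0 passed (lowest adjusted p 0.872) and 1 had an unadjusted p under 0.05, while the mixed splits gave 2 and 3 such tests. The 21 tests between the directions also gave 0 calls (lowest adjusted p 0.806). Most lists were too small to pass reliably in the EpCAM-positive-only direction. Simulated lists at 3 times its background rate were called in 41.9% of cases, at a Bonferroni cut. The EpCAM-negative-only direction was not simulated.

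**Figure D3:**
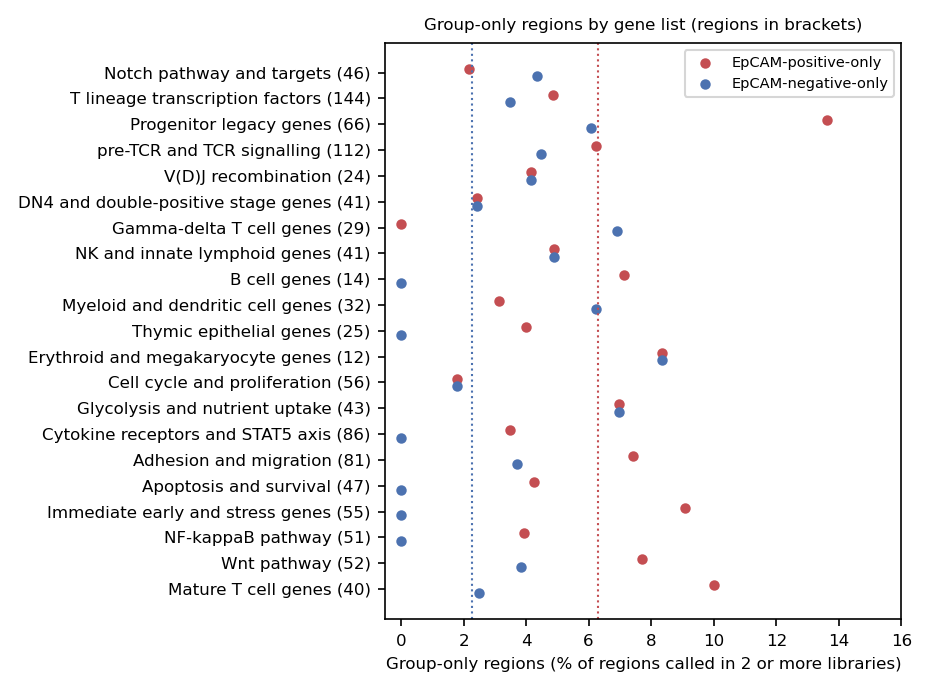
Share of each gene list's regions (x axis, percent of regions called in at least 2 libraries) that were EpCAM-positive-only (red) or EpCAM-negative-only (blue), with the number of regions in brackets; dotted lines mark the median share among regions outside the lists. Progenitor legacy genes stand at 13.6% EpCAM-positive-only, and 0 of the 42 tests passed after adjustment.

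EpCAM-positive-only regions lay at gene ends more often than EpCAM-negative-only regions. Of the former, 379 of 1594 (23.8%, 95% interval 21.7 to 25.9) had their summit within 1 kb of a gene end, among them those at Sit1, Agap2, Pik3r5, Hhex and Socs3. Of the EpCAM-negative-only regions, 53 of 623 did (8.51%, 6.44 to 11.0), among them those at Ptcra, Pknox1 and Lyl1. The odds ratio between the directions was 3.35 (Fisher's exact p = 5.54e-18), in a comparison that was not planned. Both shares were below the 48.1% of regions called in all 4 libraries (Fisher's exact p = 1.13e-81 and 4.23e-99). The mixed splits gave odds ratios of 1.49 (Fisher's exact p = 0.00983) and 0.838 (Fisher's exact p = 0.298), both nearer to 1. Regions called in 1 library showed the same order, with 21.9% and 16.9% in EpCAM-positive replicates 1 and 2 and 13.1% and 9.92% in EpCAM-negative replicates 1 and 2. Regions within genes made up 59.6% of the EpCAM-positive-only and 55.7% of the EpCAM-negative-only set.

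**Figure D4:**
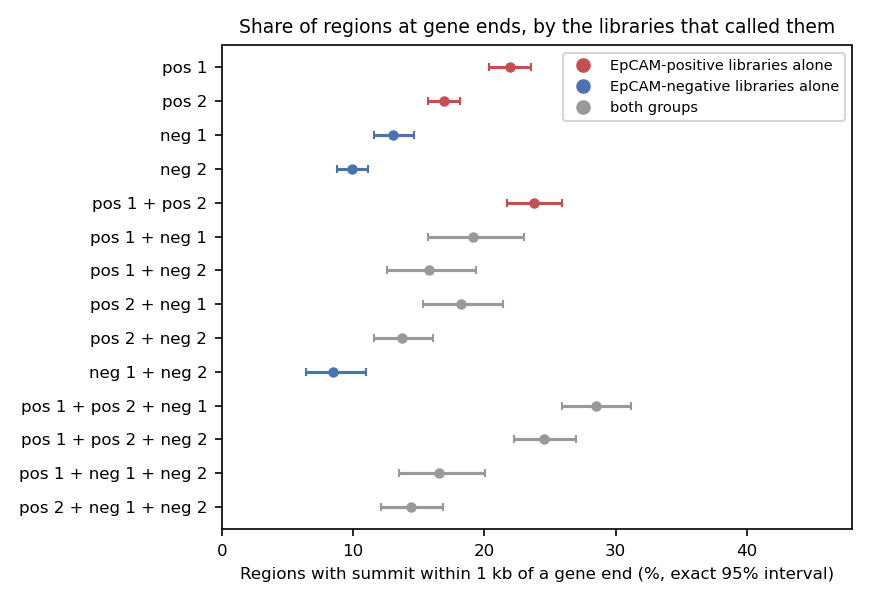
Share of regions with the summit within 1 kb of a gene end (x axis, percent, with exact 95% intervals) by the libraries that called them (rows), for regions called in 1 to 3 libraries. The EpCAM-positive pair (red) stands at 23.8% and the EpCAM-negative pair (blue) at 8.51%.

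At the level of whole lists the fractions resembled each other closely. The Jaccard index was 0.629 between the EpCAM-positive libraries and 0.614 between the EpCAM-negative ones, and 0.571 to 0.598 between libraries of different fractions. Mean overlap within fractions exceeded that between them by 0.0328, against -0.00974 and -0.0231 for the 2 mixed splits. The real split was thus the highest of 3, and the smallest share this design can give is 0.33.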

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

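Peaks on sequence scaffolds outside chromosomes 1 to 19, X and Y, which no comparison used, numbered 13 and 23 in EpCAM-positive replicates 1 and 2 and 13 and 13 in EpCAM-negative replicates 1 and 2. They were singled out because each number lies above the limit that a count of 0 allows, which says only that peaks were called there; no control library was there to set them against, and no difference between libraries was tested.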

How the results depend on the processing

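The depth-scaled set, the thinned lists and the paired peak numbers were chosen after the data had been seen, as was following the progenitor legacy list through the alternatives, picked for its low p. EpCAM-positive-only and EpCAM-negative-only regions numbered 748 and 226 with strong presence and strict absence, which removes regions by construction, and 274 and 246 in the depth-scaled set. Leaving out each library in turn gave 2835 to 5777 and 1190 to 3247, because a fraction left with 1 library needs only 1 call; for the same reason the ratio ran from 0.873 (without EpCAM-negative replicate 1), the one setting that turned its direction, to 4.85 (without EpCAM-positive replicate 1). The ratio was 1.36 at equal list length, where the longer EpCAM-positive lists lose more peaks, 1.42 after thinning and 1.11 in the depth-scaled set, and 2.38 to 3.31 under the other settings. Both counts stayed within 1.5 times of the main ones under the other 6 settings. Within-fraction overlap exceeded between-fraction overlap under all 8 alternatives run, by 0.0210 to 0.0495. The gene lists gave 0 calls under all 12, with 0 to 4 tests at an unadjusted p under 0.05. The odds ratio of the progenitor legacy list ranged from 1.04 to 5.05 and its adjusted p from 0.148 to 1. The odds ratio for gene ends was 2.84 to 3.82 under its 3 alternatives. The difference in peak number kept its direction at a −log10 q of at least 5 (2739 more peaks, exact p = 0.33). The motif search and its alternatives were not run. With the replicate number as a block, regions gained in both same-numbered pairs numbered 1594 and 623, by construction the group-only regions, and the paired differences in peak number were 1431 and 3106 (mean 2269, exact sign-flip p = 0.5, the smallest that 2 pairs can give). Nothing in the labels says that the numbers pair libraries, and same-numbered lists of different fractions overlapped at a mean Jaccard index of 0.593 and differently numbered ones at 0.584. Depth limits absence: a region under the calling level in the EpCAM-negative lists may be open there. The ratio of 1.11 after scaling cannot say for how much of the excess this holds, because that set asked for higher pileups in EpCAM-positive-only regions.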

Other observations

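Regions assigned to T cell receptor gene segments numbered 69, of which 35 were called in all 4 libraries, 25 in 1 library, 1 in the EpCAM-positive pair alone and 1 in the EpCAM-negative pair alone. Genes with group-only regions of both kinds numbered 107. Among the named genes these were Cd44, Lyl1, Tox, Tcf12, Ikzf2, Fyn, Lcp2, Zfpm1, Slc16a1, Btrc, Frmd4b, Gsx1, Xrra1, Prex1 and Sgip1. At Btrc, the EpCAM-negative-only region lay 1 bp from an EpCAM-positive peak. At Lyl1, a transcription factor gene of early progenitors, the EpCAM-negative-only region lay over the gene's end on chromosome 8 (84701388 to 84701721) and the EpCAM-positive-only region 40858 bp away (84745401 to 84745889). At Tox, an HMG-box factor of T cell development, the EpCAM-positive-only region lay 895 bp inside the gene's end on chromosome 4 (6990604 to 6990867) and the EpCAM-negative-only region 66672 bp inside (6924793 to 6925055). Whether 107 exceeds chance was not tested.

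In the depth-scaled set, the lowest p among the gene lists was that of glycolysis and nutrient uptake among EpCAM-negative-only regions (Fisher's exact p = 0.00794, adjusted p = 0.3335), and 0 lists passed. The regions at Ptcra, Lyl1, Ccr9, Etv5 and Eomes in the EpCAM-negative-only direction and at Hhex, Hes1, Fli1, Dntt, Jun and Jund in the EpCAM-positive-only direction belonged to this set. Membership rests on the pileup and not on local background, so it does not exclude depth as the reason for an absence. The Hes1 and Jun regions entered with folds over local background of 3.58 and 2.70 (Hes1) and 2.46 and 2.58 (Jun).

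The depth-scaled set was chosen after the counts had been seen; the tests of thinning, of strength and of library-wide enrichment were written before their results, with the values at equal list length and at the stricter threshold already known for both patterns. The use of the depth-scaled set and of the full lists in weighing them was settled only afterwards.

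EpCAM-positive-only regions outnumbered EpCAM-negative-only regions 1594 to 623. Against greater depth of the EpCAM-positive libraries as the whole cause stand a ratio of 1.42 (95% interval 1.29 to 1.55) after thinning, above the bound of 1.2 set beforehand, and of 1.36 (1.24 to 1.49) at equal list length. The bound was wrong as a means of excluding depth because thinning is a simulation, which assumes that pileups shrink with the background. Equal length does not equalise depth. The depth-scaled set gave 1.11 (0.934 to 1.33), an interval that includes both 1 and 1.2. Its bar was higher for EpCAM-positive-only regions: it left out Cd6 (17 and 14 summit fragments) and kept EpCAM-negative-only Cd69 (9 in each library). This pushes the ratio down, so the set cannot show how much of the excess is depth. Depth therefore stays open. A greater number of open regions in EpCAM-positive cells, the labelling and bead selection that this fraction alone underwent, and peak calling settings other than the q threshold, if they differed, cannot be told apart from depth for this count, because each goes with the fraction in both libraries. A lower q threshold for the EpCAM-negative lists would add EpCAM-negative calls and so work against this excess. The ratio of 3.28 with −log10 q of at least 5 in every list is therefore no test of it.

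EpCAM-positive-only regions were nearer to gene ends than EpCAM-negative-only regions, with an odds ratio of 3.35. An odds ratio of 3.23 (2.46 to 4.23) after thinning argues against depth as the whole cause, as far as pileups shrink with the background. Thinning is a simulation that assumes this, so depth is not excluded here either. The odds ratio was 3.97 (2.47 to 6.36) in the depth-scaled set, where 32.8% and 11.0% of regions lay at gene ends. The higher bar of that set for EpCAM-positive-only regions may have changed this value. A difference in strength between the sets is argued against by a Mantel-Haenszel odds ratio of 3.30 (2.44 to 4.48) over 7 bins of within-list percentile. A library-wide difference in enrichment at gene ends stays open. At equal list length 41.6% and 41.5% of EpCAM-positive and 40.6% and 40.3% of EpCAM-negative peaks lay there. The means were 1.10 percentage points apart, just above the bound of 1 set beforehand, so the result predicted for this cause was met. This cannot decide the question, because the lists compared include peaks of the group-only regions themselves. At equal length 25.5% of EpCAM-positive-only and 8.20% of EpCAM-negative-only regions lay at gene ends, which by itself moves the means apart. Peaks outside the group-only regions were not compared alone. In the full lists the shares were 40.3% and 38.3% against 40.6% and 39.1%, which interleave. The full lists differ in length, so this does not count against it. A gain of gene-end regions such as those at Sit1 and Hhex in EpCAM-positive cells, and the bead selection, stay open and were not tested.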
